A study of Mus musculus with 11 samples.

How the data were processed

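The study measured RNA in pieces of the mandibular arch of ICR mouse embryos on 11 Affymetrix arrays of 45101 probe sets. Per the labels, RNA was purified with a column kit and 3 ug of total RNA per sample was used to make biotinylated cRNA, and embryos were pooled by time point. Per the submitters' processing notes, the authors produced the deposited values with Affymetrix Expression Console 1.1. The algorithm is not stated in the sources used here. The deposited values are log2 signals: they lay between 0.0887 and 14.5, and the base was inferred from that range, since raw scanner values span 16 bits.

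The design written before the data were examined took the deposited values as already normalized between arrays. The values were not on a common scale, because 2 arrays (medial E10.5 replicate 1 and medial E11.5 replicate 1) had medians far below the other 9. The main values are therefore the deposited log2 values after quantile normalization across the 11 arrays, an alternative that had been written before the data were examined, and the values as deposited became an alternative. This change was made after the data were seen. The comparisons, tests, gene lists, rule for named genes and other alternatives were fixed before the data were examined.

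Probe sets were named from the table that pairs them with genes, matched to RefSeq gene names (assembly GRCm38.p6, used for names alone) by Entrez ID for 34754 probe sets. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none here, which left 18194 genes. Each gene was represented by its probe set with the highest mean. A gene was tested where at least 2 of the 8 arrays of replicated groups reached the 50th percentile of all values (4.86), which left 11968 genes.

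The replicated comparisons (medial against lateral at E10.5, and medial E11.5 against medial E10.5) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over 6 groups and 5 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Of 31 gene lists with 379 genes, 348 genes had a named probe set, and 30 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01. List p-values were adjusted over the 30 lists. The lists covered distal and proximal patterning, the endothelin axis, hedgehog, BMP, FGF, Wnt, retinoid and Notch genes, neural crest, epithelium, pharyngeal endoderm, muscle precursors, differentiated muscle, cartilage, bone, tendon, fibrillar matrix, endothelium, red cells, macrophages, neurons, glia, Hox, heart, cell cycle, Lin28 and early growth, imprinted growth, immediate early, hypoxia and sex-linked genes. With 1 array on a side, no test was made: a gene was counted where that array lay at least 2-fold beyond every array of the other group, and a list median was given as a percentile among 10000 random lists matched on mean expression.

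The rule for named genes took, per tested comparison, the 10 highest and 10 lowest log2 differences among called genes whose arrays did not overlap, without predicted or unnamed transcripts. It added every member of both patterning lists for medial against lateral tissue at E10.5, and per other list up to 4 members with the smallest adjusted p. For untested comparisons it took the 8 highest and 8 lowest differences and up to 4 members per list. Not every gene that the rule allows is named. Per list, the examples are the members with the smallest adjusted p in each direction (untested: those with the largest differences), and this narrower choice was made after the values were seen.

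Groups of arrays that share a batch were read from the signals of spiked-in control probe sets, joined into 4 groups by hierarchical clustering, after the data were seen. Batch 1 held both E9.7 arrays, medial E10.5 replicate 2, lateral E10.5 replicate 1 and medial E11.5 replicate 2. Batch 2 held the arrays of low signal, batch 3 held medial E10.5 replicate 3 and lateral E10.5 replicates 2 and 3, and batch 4 held the E14.5 array. Alternatives were other scalings, filters, summaries of probe sets, thresholds, variance models, array weights, the replicate number as a block, an estimated correlation for camera, and leaving out each array in turn. Added after the data were seen were the values as deposited, batch as a fixed effect, arrays of the same batch alone, list tests on centred values, and fits without the arrays of low signal.

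The procedure was tested on simulated data with known changes in 11968 genes. For medial against lateral at E10.5, it recovered 40.3% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold, and it called 5 unchanged genes. For E11.5 against E10.5 it recovered 23.9%, 68.7% and 95.5%, and it called 4 unchanged genes. The simulated noise was independent between genes and arrays, without batches or arrays of low signal. These shares and false calls may therefore not hold for the real data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a gene symbol or with several symbols were left out, because their values cannot be given to 1 gene.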

Results

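Gene expression was measured in mandibular arch tissue of ICR mouse embryos on 11 Affymetrix arrays. The arch was divided into a medial piece, taken at its distal end, and a lateral piece that held the rest, and the stated purpose of the series was to compare gene expression between these pieces. Medial and lateral tissue were each represented by 1 array at E9.7 and by 3 arrays at E10.5. Medial tissue was also measured on 2 arrays at E11.5 and on 1 array at E14.5. The E14.5 sample is labelled as tongue and as the anterior part, so stage and dissection differ together there. RNA was pooled from 40 embryos per time point, and p-values therefore measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. The median deposited log2 signal was between 5.20 and 5.73 on 9 arrays and was 2.37 on medial E10.5 replicate 1 and 2.47 on medial E11.5 replicate 1. After quantile normalization these arrays also had the highest signal of an 18S rRNA control probe set, 11.8 and 11.4 against 7.51 to 9.32 on the others. They are 1 of 3 and 1 of 2 replicates of groups tested here, and it is not known whether their values were computed in another way.

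At E10.5, medial tissue was set apart from lateral tissue by opposite sets of patterning genes. The largest difference was that of Rgs5, a regulator of G-protein signalling, which was higher in medial tissue by 5.36 ± 0.16 (log2 ± SE, n = 3 per side, limma adjusted p = 1.57e-06). Alx1, a homeobox gene of craniofacial mesenchyme, was higher by 4.75 ± 0.26 (adjusted p = 2.45e-05), and Cavin2, which encodes a protein of caveolae, by 3.64 ± 0.18 (adjusted p = 1.88e-05). The Wnt antagonist gene Dkk1 was higher by 3.15 ± 0.16 (adjusted p = 2.18e-05). In the other direction, Dlx1as differed by -5.35 ± 0.23 (adjusted p = 1.07e-05), and the homeobox genes Shox2 and Gbx2 by -4.70 ± 0.19 (adjusted p = 6.94e-06) and -3.98 ± 0.18 (adjusted p = 1.37e-05). The other genes with the largest medial excess were Nhlh2 (3.19), Hand1 (3.17), Gata3 (3.08), Synpo2 (3.01), Ndnf (2.93) and Isl1 (2.80). Those with the largest lateral excess were Barx1 (-3.47), Dlx6os1 (-3.33), Sim2 (-3.32), Emx2 (-3.17), Col8a2 (-3.13), Smoc2 (-2.94) and Dlx1 (-2.89). For Rgs5, Alx1, Cavin2, Nhlh2, Gata3, Dlx1as, Shox2, Gbx2, Sim2, Emx2, Col8a2 and Smoc2 the mean of the lower tissue lay under the filter level of 4.86 (the 50th percentile of all values), as it did for Alx4, Pou3f3 and Fgf8 below. The size and rank of such differences rest on dim signal and are uncertain, here and in the other comparisons.

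In total, 554 of 11968 tested genes differed at E10.5, 338 higher and 216 lower in medial tissue, and 145 and 106 of these by at least 2-fold. At an unadjusted p under 0.05 the count was 1927. In all 554 genes the medial and lateral arrays did not overlap; among all tested genes this held for 2989, where chance gives 10%. The count was 313 without lateral replicate 2 and 308 without lateral replicate 3. It was 358 with each array centred on its median, which shifted the median of all genes by 0.12, and 1254 with control-probe batch as a fixed effect. With array weights it was 2816, of which 1317 were higher and 1499 lower. Within the batches that held both groups, the median ratio of the log2 difference to the pooled difference over the 554 called genes was 0.954 in batch 1 and 1.07 in batch 3. The same arrays entered the pooled difference and the calls, so ratios near 1 are largely built in and do not exclude an effect of batch.

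Of 11 measured distal patterning genes, 9 were higher in medial tissue and none was lower, over all genes and also adjusted over the list alone (camera adjusted p = 1.16e-12, and adjusted p = 0.0398 with an estimated correlation). Epithelial and endothelial markers were higher in the same medial pieces. The list median was 1.45, and it was 1.72 within batch 1 and 1.38 within batch 3. Besides Hand1, Gata3 and Isl1, the members that passed were Bmp4 (1.96 ± 0.18), Msx2 (1.61 ± 0.24), Hand2 (1.45 ± 0.16), Alx4 (0.74 ± 0.17), Msx1 (0.73 ± 0.17) and Tbx3 (0.52 ± 0.11). Tbx2 at -0.39 ± 0.22 (adjusted p = 0.449) and Gata2 at 0.36 ± 0.21 (adjusted p = 0.456) did not pass. Leaving out 1 array ended 3 of these calls. Alx4 did not pass without medial replicate 2 (adjusted p = 0.165) or 3 (0.120) or without lateral replicate 1 (0.107), 2 (0.204) or 3 (0.124). Msx1 did not pass without medial replicate 2 (adjusted p = 0.151) or 3 (0.111) or without lateral replicate 1 (0.137), 2 (0.153) or 3 (0.112). Tbx3 did not pass without medial replicate 1 (adjusted p = 0.0569), 2 (0.0827) or 3 (0.0663) or without lateral replicate 1 (0.101), 2 (0.123) or 3 (0.0794). Alx4 also did not pass with each array centred on its median (adjusted p = 0.115), without the filter on dim genes (0.0631), with the trend and robust options (0.0859), with only the groups compared (0.0623) or with the replicate number as a block (0.0684). Msx1 did not pass without the filter (adjusted p = 0.0575) or with only the groups compared (0.0616), and Tbx3 did not pass with centring (adjusted p = 0.209) or with the mean of its probe sets (0.0679). With the mean of its probe sets, Gata2 passed (adjusted p = 0.0342).

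Of 12 measured proximal patterning genes, 7 were lower in medial tissue and 1 was higher; adjusted over the list alone these counts were 9 and 2 (camera adjusted p = 1.12e-06, and adjusted p = 0.149 with an estimated correlation). The list median was -1.64, and it was -1.37 within batch 1 and -2.28 within batch 3. Besides Barx1 and Dlx1, the lower members were Pou3f3 (-2.61 ± 0.33), Dlx2 (-2.29 ± 0.15), Fgf8 (-1.93 ± 0.34), Dlx5 (-1.73 ± 0.28) and Lhx6 (-1.55 ± 0.27). The homeobox gene Meis2 was the member that was higher in medial tissue (0.93 ± 0.12, adjusted p = 0.00222). Dlx6 at -1.32 ± 0.37, Lhx8 at -0.86 ± 0.26, Eya1 at 0.54 ± 0.17 and Gsc at -0.22 ± 0.16 did not pass. Without medial replicate 1, Dlx6 (adjusted p = 0.0255) and Eya1 (adjusted p = 0.0113) passed. Fgf8 did not pass without lateral replicate 1 (adjusted p = 0.0539) or 2 (0.0524), and Lhx6 did not pass without lateral replicate 2 (adjusted p = 0.0572) or 3 (0.0587). Dlx6 passed with centring (adjusted p = 0.0219), array weights (0.00496) and batch as a fixed effect (0.0370). Eya1 passed with array weights (adjusted p = 0.00195), batch (0.0485) and without the arrays of low signal (0.0102), and Lhx8 with array weights (adjusted p = 0.0142) and batch (0.00926).

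**Figure D1:**
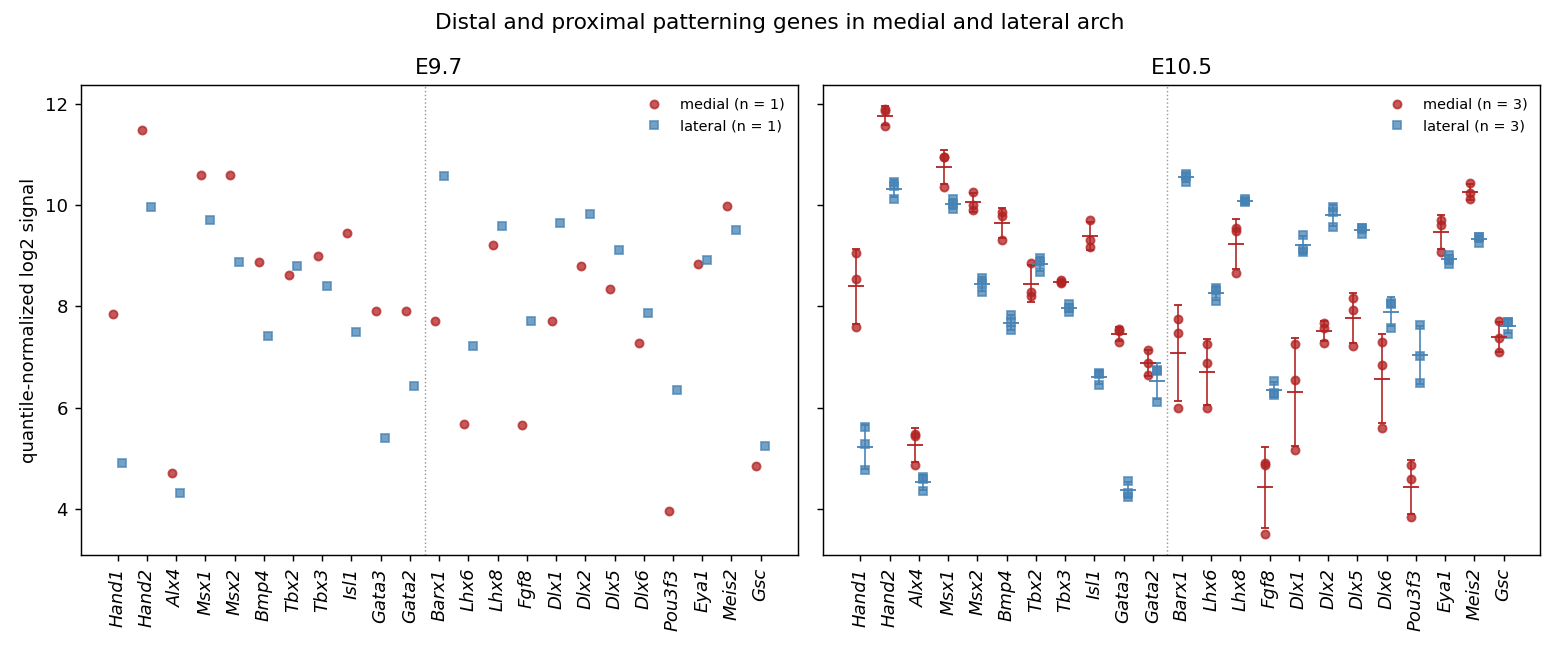
Quantile-normalized log2 signal of each array for the tested distal (left of the dotted line) and proximal patterning genes at E9.7 and E10.5, with mean and SD where n = 3. At E10.5, 9 of 11 distal genes were higher and 7 of 12 proximal genes lower in medial tissue.

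Signalling lists differed as well at E10.5. Of 12 BMP ligand, antagonist and feedback genes, 7 were higher in medial tissue (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.59e-11, and adjusted p = 0.0384 with an estimated correlation), among them Bambi (1.74 ± 0.13) and Id4 (1.74 ± 0.14), a target of BMP signals. Of 8 hedgehog genes, 5 were higher (7 adjusted over the list alone; camera adjusted p = 3.83e-10, and adjusted p = 0.149 with an estimated correlation), including the ligand gene Shh (1.62 ± 0.14) and the forkhead gene Foxf2 (2.06 ± 0.18). Of 13 FGF genes, 3 were lower in medial tissue, and likewise 3 adjusted over the list alone (camera adjusted p = 0.000442, and adjusted p = 0.178 with an estimated correlation). Besides the ligand gene Fgf8 these were the feedback genes Spry1 (-1.45 ± 0.13) and Dusp6 (-1.32 ± 0.17). Of 8 retinoid genes, 2 were lower and 1 was higher (4 and 2 adjusted over the list alone; camera adjusted p = 0.0281, and adjusted p = 0.163 with an estimated correlation). Cyp26a1, which encodes an enzyme that degrades retinoic acid, was lower by -2.26 ± 0.12, Aldh1a2, which encodes an enzyme that makes it, was lower by -1.30 ± 0.17, and Dhrs3 was higher by 0.78 ± 0.11. Pooled list medians, with those within batches 1 and 3 in brackets, were 0.97 (0.77, 1.08) for BMP, 1.32 (1.24, 1.69) for hedgehog, -0.35 (-0.31, -0.39) for FGF and -0.47 (-0.37, -0.58) for retinoid genes. Without medial replicate 3 the retinoid list had adjusted p = 0.0863. With each array centred on its median, Dhrs3 did not pass (adjusted p = 0.0670).

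Tissue lists also differed at E10.5. Of 16 epithelial genes, 10 were higher in medial tissue (11 adjusted over the list alone; camera adjusted p = 2.37e-11, and adjusted p = 0.0384 with an estimated correlation), led by the keratin genes Krt18 (1.49 ± 0.15) and Krt8 (1.34 ± 0.14). Of 12 endothelial genes, 3 were higher (4 adjusted over the list alone; camera adjusted p = 6.61e-06, and adjusted p = 0.0384 with an estimated correlation), among them Cldn5 (0.67 ± 0.11) and Emcn (0.76 ± 0.14). Of 6 pharyngeal endoderm genes, 3 were higher (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00440, and adjusted p = 0.130 with an estimated correlation), among them Foxa1 (1.06 ± 0.13) and Foxa2 (0.95 ± 0.11). Of 13 fibrillar matrix genes, 3 were higher and 1 was lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.631 with an estimated correlation), with Lum at 1.95 ± 0.20, Postn at 1.52 ± 0.17 and Fbln5 at -1.21 ± 0.16. Of 9 imprinted growth genes, 2 were higher (4 adjusted over the list alone; camera adjusted p = 0.00276, and adjusted p = 0.449 with an estimated correlation), Plagl1 (1.59 ± 0.14) and Igf2 (0.80 ± 0.10). Pooled list medians, with those within batches 1 and 3 in brackets, were 0.78 (0.63, 0.77) for epithelium, 0.41 (0.42, 0.46) for endothelium, 0.53 (0.38, 0.72) for endoderm, 0.22 (0.31, 0.29) for matrix and 0.41 (0.72, 0.54) for imprinted genes. The matrix list lost its call without medial replicate 2 (adjusted p = 0.176), medial replicate 3 (adjusted p = 0.185) or lateral replicate 1 (adjusted p = 0.0991). The endoderm list lost it without medial replicate 3 (adjusted p = 0.0555) and with each array centred on its median (adjusted p = 0.0540). Cldn5 did not pass without lateral replicate 2 (adjusted p = 0.0555), and Emcn did not pass without medial replicate 3 (adjusted p = 0.0518) or without lateral replicate 1 (0.0519), 2 (0.0776) or 3 (0.0693). With centring, Cldn5 did not pass (adjusted p = 0.107). The matrix list was not called with the mean of the probe sets (adjusted p = 0.0557) or with the replicate number as a block (0.0909).

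The other tested lists were not called at E10.5, although 5 of them were called under other processing. Of 19 Wnt genes, 2 were higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0923), and without medial replicate 1 the Wnt list was called (adjusted p = 0.00197). Of 9 endothelin axis genes, 2 were higher and 3 lower (2 and 4 adjusted over the list alone; adjusted p = 0.277). Of 9 Notch genes, 1 was higher (1 and 1 lower adjusted over the list alone; adjusted p = 0.878). Of 13 neural crest genes, 2 were lower (3 higher and 3 lower adjusted over the list alone; adjusted p = 0.935). Of 8 muscle precursor genes, 1 was higher and 2 lower (2 and 3 adjusted over the list alone; adjusted p = 0.935), and of 21 genes of differentiated muscle 2 and 1 (2 and 5 adjusted over the list alone; adjusted p = 0.351). Of 9 cartilage genes, 2 were lower, and likewise adjusted over the list alone (adjusted p = 0.121), and without lateral replicate 2 the list was called (adjusted p = 0.0277). Of 5 tendon genes, 1 was higher and 1 lower (1 and 2 adjusted over the list alone; adjusted p = 0.878), and of 3 glial genes 1 was lower (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.169), namely Fabp7 (-2.06 ± 0.14). With each array centred on its median, the endothelin axis (adjusted p = 0.00398), Wnt (0.00625), differentiated muscle (0.0431), cartilage (0.0224) and glial lists (0.0110) were called. Without the filter on dim genes, the cartilage (adjusted p = 0.0356) and glial lists (0.00453) were called, and with the mean of the probe sets the Wnt (adjusted p = 0.0215), cartilage (0.0427) and glial lists (0.0251). The Wnt list was also called without the arrays of low signal (adjusted p = 0.0397) and with batch as a fixed effect (0.0160).

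For 6 neuronal genes the counts at E10.5 were 2 higher and 0 lower (adjusted p = 0.327), for 7 Lin28 and early growth genes 1 and 1 (adjusted p = 0.878), for 9 immediate early genes 1 and 1 (adjusted p = 0.878) and for 8 hypoxia genes 1 and 0 (adjusted p = 0.607), with the same counts adjusted over the list alone. No member passed among 3 bone genes (adjusted p = 0.311), 9 red cell genes (adjusted p = 0.607), 5 Hox genes (adjusted p = 0.889), 19 cell cycle genes (adjusted p = 0.327) and 4 sex-linked genes (adjusted p = 0.607), nor adjusted over the list alone. Of 8 macrophage genes none passed (1 higher adjusted over the list alone; adjusted p = 0.878). The heart list had 2 measured genes, too few for the list test. Median and mean differed in sign for muscle precursors (-0.17 and 0.15), neurons (-0.05 and 0.38), hypoxia (-0.01 and 0.12) and Notch genes (0.00 and -0.01). For macrophages the median was -0.0005 and the test pointed up, and for muscle precursors the test pointed down. Centring each array on its median turned the sign of the medians of the neural crest, red cell, macrophage, cell cycle, Lin28 and hypoxia lists.

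At E9.7, with 1 array per side and no test, the same patterning lists stood apart. Of 10 distal patterning genes, 7 were at least 2-fold higher in medial tissue (list median 1.5, at percentile 100 of matched random lists), with Hand1 at 2.94, Gata3 at 2.50 and Isl1 at 1.95. Of 12 proximal genes, 6 were at least 2-fold lower (list median -0.90, percentile 0), with Barx1 at -2.86 and Pou3f3 at -2.38. The hedgehog list had 5 of 8 genes higher (median 1.09), including Foxf1 (2.50), and the BMP list 5 of 11 (median 0.88), including Bambi (1.80). The FGF list had 3 of 12 genes lower (median -0.56), with Fgf8 at -2.05. Epithelial genes had a median of 0.47 with 3 of 15 higher, and endothelial genes 0.74 with 1 of 12 higher. The hedgehog, BMP, Wnt, epithelial, endoderm, endothelial and imprinted growth lists were at percentile 100 too. The FGF and endothelin axis lists were at percentile 0 and the immediate early list at 99.6. Such percentiles were thus not particular to the patterning lists. Over all genes, the largest differences were those of Rgs5 (4.32), Pmp22 (3.24), Ndnf (3.20) and Dkk1 (3.13) in one direction and Smoc1 (-3.51), Gbx2 (-3.31) and Vgll2 (-2.97) in the other.

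In total, 198 of 11252 genes were at least 2-fold apart at E9.7, 123 higher and 75 lower in medial tissue. Between 2 arrays of the same group this count was 3 to 57 in the 4 pairs without an array of low signal and 166 to 281 in the 3 pairs with such an array. Both E9.7 arrays belonged to control-probe batch 1.

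The medial-lateral differences of the 2 stages, which share no arrays, were related across 12235 genes (Pearson r = 0.635, Spearman rho = 0.385), and genes are not independent replicates. Over the 9 pairs of E10.5 arrays r was between 0.415 and 0.655. Of 552 genes called at E10.5 and measured at both stages, 516 (93.5%) had the same sign at E9.7, namely 321 of 336 higher and 195 of 216 lower in medial tissue. Among the called genes that were also at least 2-fold apart at E9.7, all 154 had the same sign. The median ratio of the E9.7 difference to the E10.5 difference over the called genes was 0.634. Selection of the genes at E10.5 alone can lower this ratio, so it does not show that the differences were smaller at E9.7.

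**Figure D2:**
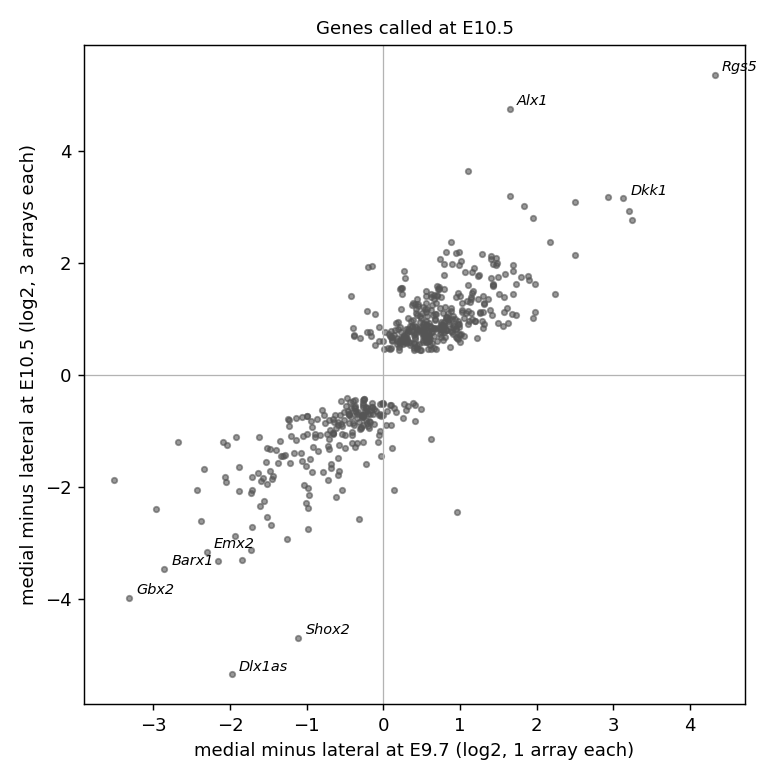
Log2 difference between medial and lateral tissue at E9.7 (1 array each) against that at E10.5 (3 arrays each), for genes called at E10.5. The sign was the same in 516 of the 552 genes measured at both stages.

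Between E10.5 and E11.5, medial tissue gained muscle genes and lost patterning genes of the distal list and part of the proximal list. The alpha-actin gene Actc1 rose by 5.84 ± 0.26 (log2 ± SE, n = 2 against 3, limma adjusted p = 6.65e-06), the muscle regulatory gene Myog by 5.48 ± 0.23 (adjusted p = 5.85e-06) and the slow troponin gene Tnnt1 by 5.30 ± 0.17 (adjusted p = 1.55e-06). Agtr2, which encodes an angiotensin receptor, rose by 5.60 ± 0.17 (adjusted p = 1.55e-06). The chemokine gene Cxcl14 (-5.84 ± 0.29, adjusted p = 1.32e-05), Dkk1 (-4.45 ± 0.18, adjusted p = 5.85e-06) and the homeobox gene Msx2 (-4.13 ± 0.27, adjusted p = 4.06e-05) fell. The other genes with the largest rises were Myl1 (5.08), Acta2 (4.95), Thbs4 (4.80), Smoc2 (4.52), Pgm5 (4.48) and Meox2 (4.28). The other largest falls were those of Dlx5 (-3.92), Msx1 (-3.47), Igdcc3 (-3.37), Mab21l1 (-3.34), Lhx8 (-3.27), Dlx6 (-2.96) and Tbx2 (-2.88). For Myog, Agtr2, Myl1, Thbs4, Smoc2, Meox2, Cxcl14, Dlx5, Mab21l1 and Dlx6 the mean of the lower stage lay under the filter level, so the size and rank of these changes are uncertain.

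In total, 828 of 11968 genes changed from E10.5 to E11.5, 517 up and 311 down, and 291 and 131 of these by at least 2-fold. At an unadjusted p under 0.05 the count was 2155. In all 828 genes the arrays of the stages did not overlap; among all tested genes this held for 3396, where chance gives 20%. The count was 520 without E11.5 replicate 1 and 511 without E11.5 replicate 2, with 254 up and 257 down in the latter. It was 455 with each array centred on its median, 482 with only these groups in the fit and 2182 with control-probe batch as a fixed effect. The median ratio of the log2 change to the pooled change over the 828 called genes was 1.02 within batch 1 and 0.992 within batch 2. Here too the same arrays entered the pooled change and the calls, so ratios near 1 are largely built in.

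Of 21 genes of differentiated muscle, 19 rose and none fell (20 rose adjusted over the list alone; camera adjusted p = 3.26e-28, and adjusted p = 0.0385 with an estimated correlation), with a list median of 2.52, 3.14 within batch 1 and 2.00 within batch 2. A gene under the filter level on all E10.5 arrays could enter the test only by being higher on both E11.5 arrays. For such members the filter set the direction. Of the 26 listed muscle genes, 11 reached that level on at least 1 medial array of E9.7 or E10.5. Of 8 muscle precursor genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 1.34e-10, and adjusted p = 0.0385 with an estimated correlation), among them Myod1 (4.13 ± 0.18) and Tcf21 (3.16 ± 0.16). Isl1, the member that fell (-0.81 ± 0.19), was chosen after its value was seen. Of 13 fibrillar matrix genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 9.55e-08, and adjusted p = 0.154 with an estimated correlation), with Postn at 2.01 ± 0.19, Ogn at 2.16 ± 0.21 and Lum at -2.01 ± 0.22. Of 5 tendon genes, 3 rose, and likewise adjusted over the list alone (camera adjusted p = 0.00160, and adjusted p = 0.0571 with an estimated correlation), with Thbs4 and Tnc (1.27 ± 0.21). Of 8 macrophage genes, 4 rose (6 adjusted over the list alone; camera adjusted p = 6.19e-05, and adjusted p = 0.0486 with an estimated correlation), with Mrc1 at 1.68 ± 0.17 and C1qa at 0.97 ± 0.12. Pooled list medians, with those within batches 1 and 2 in brackets, were 2.61 (2.72, 2.46) for muscle precursors, 1.21 (1.40, 1.20) for matrix, 1.19 (0.97, 1.09) for tendon and 0.78 (0.79, 0.61) for macrophages. Tnc did not pass without E11.5 replicate 2 (adjusted p = 0.0598). Isl1 did not pass without medial E10.5 replicate 2 (adjusted p = 0.0759) or 3 (0.0780) or without E11.5 replicate 1 (0.213). Isl1 also did not pass with centring (adjusted p = 0.0542), with only the groups compared (0.114), with array weights (0.0817) or without the arrays of low signal (0.106).

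In the same medial tissue, muscle and macrophage markers rose and epithelial and endothelial markers fell. Of 11 distal patterning genes, 7 fell from E10.5 to E11.5 and none rose (10 fell adjusted over the list alone; camera adjusted p = 8.76e-12, and adjusted p = 0.0391 with an estimated correlation), and the list median was -1.0, -1.08 within batch 1 and -0.79 within batch 2. Of 12 proximal patterning genes, 6 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.000150, and adjusted p = 0.161 with an estimated correlation). Dlx2 fell (-2.73 ± 0.16) and Pou3f3, a POU-domain gene, rose (3.88 ± 0.37), as did Gsc (0.77 ± 0.18), which was chosen after its value was seen. Of 16 epithelial genes, 12 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 1.01e-09, and adjusted p = 0.0385 with an estimated correlation), with Cldn7 at -1.58 ± 0.14 and Krt14 at -2.03 ± 0.19. Krt15, the member that rose (1.99 ± 0.29), was chosen after its value was seen. Of 12 endothelial genes, 2 fell (4 adjusted over the list alone; camera adjusted p = 4.49e-05, and adjusted p = 0.0391 with an estimated correlation), Cldn5 (-0.87 ± 0.12) and Tek (-0.84 ± 0.17). Of 7 Lin28 and early growth genes, 4 fell (5 adjusted over the list alone; camera adjusted p = 2.80e-06, and adjusted p = 0.0571 with an estimated correlation), with Sall4 at -1.49 ± 0.13 and Mycn at -0.96 ± 0.12, whose probe sets differed in sign. Of 8 hypoxia and glycolysis genes, 3 fell (4 adjusted over the list alone; camera adjusted p = 6.19e-05, and adjusted p = 0.0571 with an estimated correlation), with Slc2a1 at -0.68 ± 0.14 and Ldha at -0.66 ± 0.15. No cell cycle gene of 19 passed, nor adjusted over the list alone, while the list was called as lower (camera adjusted p = 0.00255, and adjusted p = 0.0571 with an estimated correlation; median -0.18). Pooled list medians, with those within batches 1 and 2 in brackets, were -1.30 (-1.61, -1.41) for proximal patterning, -0.83 (-0.79, -0.90) for epithelium, -0.38 (-0.27, -0.39) for endothelium, -0.96 (-0.94, -1.03) for Lin28, -0.61 (-0.46, -0.72) for hypoxia and -0.18 (-0.20, -0.19) for cell cycle genes. Gsc did not pass without medial E10.5 replicate 1 (adjusted p = 0.0730) or 3 (0.0839) or without E11.5 replicate 1 (0.0852) or 2 (0.179). Tek did not pass without E11.5 replicate 1 (adjusted p = 0.105). Slc2a1 did not pass without medial E10.5 replicate 2 (adjusted p = 0.0624) or without E11.5 replicate 1 (0.0852) or 2 (0.0751), and Ldha did not pass without the same arrays (0.0624, 0.0692 and 0.139). With each array centred on its median, Gsc (adjusted p = 0.408), Tek (0.0955), Slc2a1 (0.248) and Ldha (0.344) did not pass. With only the groups compared, Gsc (adjusted p = 0.119), Tek (0.0640), Slc2a1 (0.0534) and Ldha (0.124) did not pass. With array weights, Gsc (adjusted p = 0.275), Krt15 (0.0641), Slc2a1 (0.0512) and Ldha (0.0591) did not pass. Without the arrays of low signal, Gsc (adjusted p = 0.126), Krt15 (0.0764), Tek (0.0612) and Slc2a1 (0.113) did not pass. Gsc did not pass without the filter on dim genes (adjusted p = 0.0524), and Mycn did not pass with the mean of its probe sets (-0.42, adjusted p = 0.113).

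Several signalling lists were called between E10.5 and E11.5. Of 12 BMP genes, 3 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0118, and adjusted p = 0.199 with an estimated correlation), with Bambi at -2.57 ± 0.15, Id4 at -1.78 ± 0.15 and Bmp2 at 1.14 ± 0.21. Of 19 Wnt genes, 6 fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.00596, and adjusted p = 0.163 with an estimated correlation), with the antagonist genes Dkk1 and Dkk2 (-2.15 ± 0.21) among those that fell. Of those that rose, Wnt11 (1.11 ± 0.20) and Sfrp1 (0.91 ± 0.16) were chosen after their values were seen. Of 8 retinoid genes, 4 rose, and likewise adjusted over the list alone (camera adjusted p = 0.00608, and adjusted p = 0.0742 with an estimated correlation), with Aldh1a2 at 2.24 ± 0.19 and Cyp26b1 at 1.15 ± 0.16. Of 9 Notch genes, 3 rose (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00993, and adjusted p = 0.255 with an estimated correlation), with Hey1 at 0.89 ± 0.13 and Dll1 at 1.75 ± 0.31. Of 8 hedgehog genes, 2 rose, and likewise adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.378 with an estimated correlation), Foxd1 (0.98 ± 0.15) and Foxf2 (0.86 ± 0.20). Pooled list medians, with those within batches 1 and 2 in brackets, were -0.36 (-0.28, -0.40) for BMP, -0.29 (-0.48, -0.21) for Wnt, 0.59 (0.63, 0.68) for retinoid, 0.40 (0.32, 0.30) for Notch and 0.40 (0.50, 0.66) for hedgehog genes. Without medial E10.5 replicate 1 the hedgehog list was not called (adjusted p = 0.122), nor was it without E11.5 replicate 2 (0.183). The BMP list was not called without medial E10.5 replicate 3 (adjusted p = 0.0549) or E11.5 replicate 2 (0.0504), and the Notch list was not called without E11.5 replicate 2 (adjusted p = 0.0896). Bmp2 did not pass without E11.5 replicate 1 (adjusted p = 0.0844) or 2 (0.0693), nor did Foxf2 (0.0789 and 0.166), and Dll1 did not pass without E11.5 replicate 2 (adjusted p = 0.0534). The BMP list was also not called with the replicate number as a block (adjusted p = 0.123) or with batch as a fixed effect (0.0873), and the Notch list was not called without the filter on dim genes (adjusted p = 0.0692). Foxf2 changed by 0.23 with the mean of its probe sets (adjusted p = 0.425) and did not pass with centring (0.158), only the groups compared (0.0885), array weights (0.111) or without the arrays of low signal (0.0562). With centring, Foxd1 (adjusted p = 0.0853), Hey1 (0.0955) and Sfrp1 (0.135) did not pass. Sfrp1 did not pass with only the groups compared (adjusted p = 0.0533), nor Bmp2 without the arrays of low signal (0.0621).

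Of 3 glial genes, 1 rose from E10.5 to E11.5 (2 adjusted over the list alone; camera adjusted p = 0.00727, and adjusted p = 0.0809 with an estimated correlation), Erbb3 (1.78 ± 0.19). Of 9 cartilage genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.332 with an estimated correlation), with Hapln1 at -2.14 ± 0.21 and Col9a2 at 1.57 ± 0.33, and the list median of -0.16 was 0.10 within batch 1 and -0.84 within batch 2. The cartilage list lost its call without medial E10.5 replicate 1 (adjusted p = 0.0594) and without E11.5 replicate 1 (adjusted p = 0.623). Col9a2 did not pass without medial E10.5 replicate 1 (adjusted p = 0.0542) or 3 (0.0559) or without E11.5 replicate 2 (0.0918). Col9a2 also did not pass with only the groups compared (adjusted p = 0.0565) or with array weights (0.0748). The cartilage list was not called without the filter on dim genes (adjusted p = 0.0944) or without the arrays of low signal (0.796). The neuronal list was at the threshold (adjusted p = 0.05, and adjusted p = 0.275 with an estimated correlation): 3 of 6 genes rose and 1 fell (3 and 2 adjusted over the list alone), with Nefm at 2.90 ± 0.18, Nefl at 3.48 ± 0.24 and Gap43 at -1.88 ± 0.22. It was called without medial E10.5 replicate 1 (adjusted p = 0.0223) and without medial E10.5 replicate 3 (adjusted p = 0.0262). It was also called with centring (adjusted p = 0.000141) and with the mean of the probe sets (0.0263).

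The remaining lists were not called between E10.5 and E11.5. Of 9 endothelin axis genes, 2 rose and 4 fell (adjusted p = 0.170), of 13 neural crest genes 2 and 4 (adjusted p = 0.160), of 6 pharyngeal endoderm genes 2 and 1 (adjusted p = 0.474) and of 9 immediate early genes 1 and 1 (adjusted p = 0.70), with the same counts adjusted over the list alone. The sign of the endoderm median turned when each array was centred on its median. No member passed among 5 Hox genes (adjusted p = 0.168) and 4 sex-linked genes (adjusted p = 0.764), nor adjusted over the list alone, and among 3 bone genes none passed (1 rose adjusted over the list alone; adjusted p = 0.158). Of 13 FGF genes, 1 rose (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.185), of 9 red cell genes 1 fell (2 adjusted over the list alone; adjusted p = 0.133), and of 9 imprinted growth genes 1 rose, and likewise adjusted over the list alone (adjusted p = 0.124). Without E11.5 replicate 1 the FGF, red cell and imprinted growth lists were called (adjusted p = 0.0499, 0.00208 and 0.00505), and without medial E10.5 replicate 2 the imprinted growth list was called (adjusted p = 0.0442). The imprinted growth list was also called with the mean of the probe sets (adjusted p = 0.00651), the replicate number as a block (0.0467), centring (0.0180), batch as a fixed effect (0.0237) and without the arrays of low signal (0.0218). Without those arrays, the FGF (adjusted p = 0.00291) and red cell lists (0.00141) were called. The endothelin axis list was called with centring (adjusted p = 0.00240) and the Hox list without the filter on dim genes (0.0170). Of 2 heart genes, 1 rose, and the list was too small for the list test. The immediate early list had a median of -0.06, a mean of 0.0006 and a test that pointed down.

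**Figure D3:**
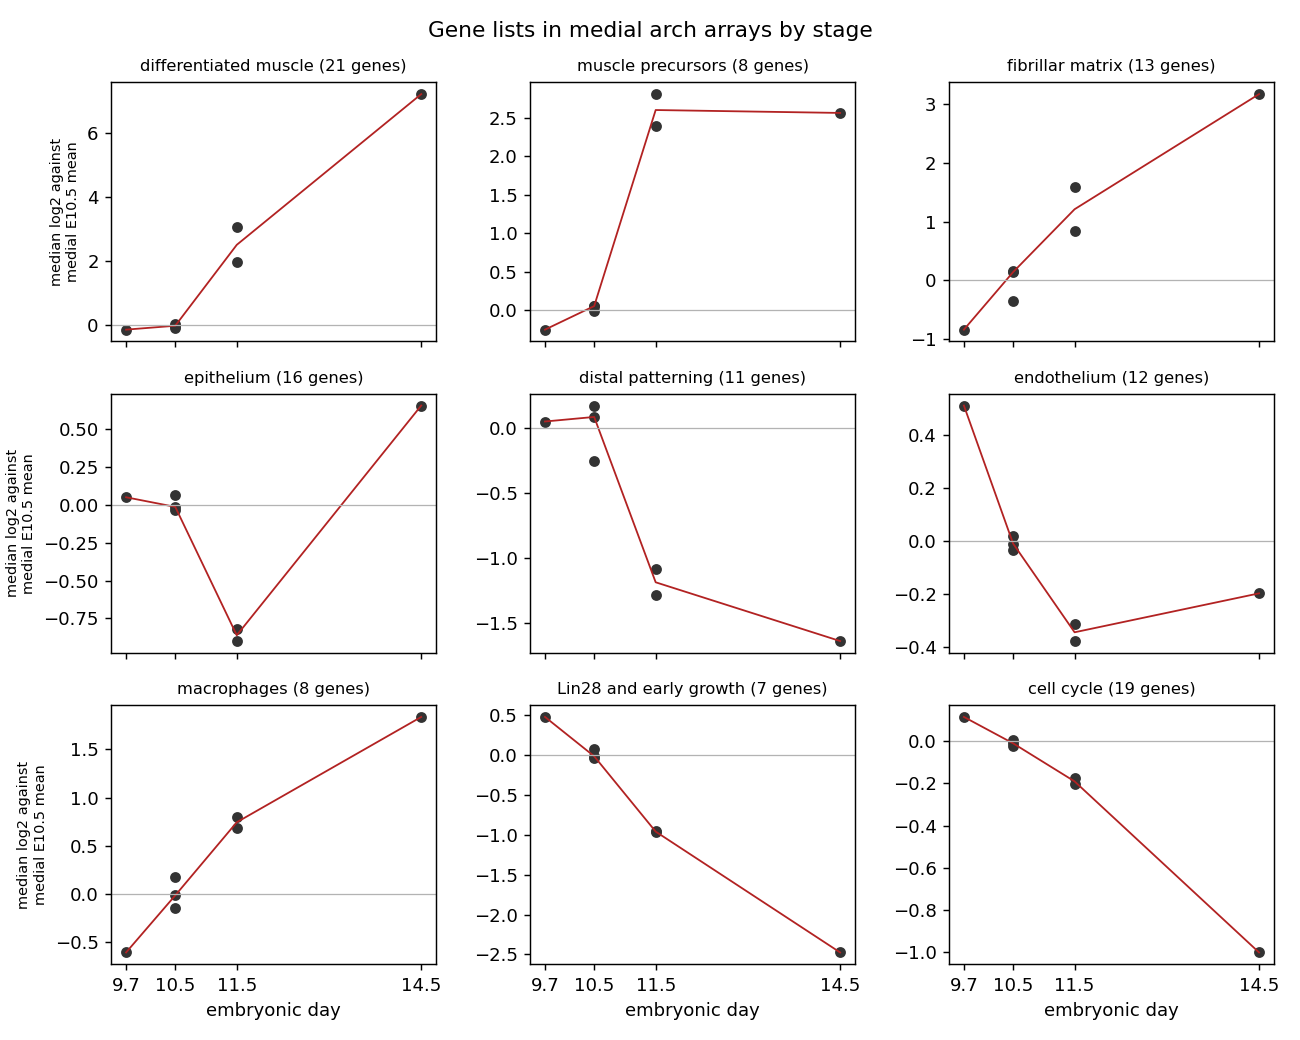
Median log2 signal of each list in each medial array against the mean of the medial E10.5 arrays, by embryonic day, with a line through the medians per stage. The median gene difference between E11.5 and E10.5 was 2.52 for differentiated muscle and -1.0 for distal patterning, and the E14.5 array is labelled as tongue.

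The E14.5 sample was set against E11.5 without a test. Of 26 genes of differentiated muscle, 24 lay at least 2-fold above both E11.5 arrays and 1 below (list median 4.24), with Tnnt3 at 6.49 and Myl4 at 6.42, although the other measured probe set of Myl4 differed by 0.31. Fibrillar matrix genes were higher in 9 of 13 (median 2.30; Col6a3 at 3.91), epithelial genes in 10 of 16 (median 1.61; the keratin genes Krt14 at 5.15 and Krt5 at 4.51) and macrophage genes in 7 of 11 (median 1.32; Lyz2 at 1.99). Glial genes were higher in 3 of 5 (median 1.70; Fabp7 at 3.00) and immediate early genes, which respond to handling, in 5 of 10 (median 1.29; Egr1 at 2.64). Red cell genes were lower in 6 of 9 (median -1.33), with the embryonic globin genes Hbb-bh1 at -7.26 and Hba-x at -4.49. Lin28 and early growth genes were lower in 4 of 6 (median -1.76; Sall4 at -2.72, with its other probe set at -0.91), cell cycle genes in 2 of 19 (median -0.79; Aurka at -1.32) and distal patterning genes in 5 of 10 with 1 higher (median -0.87; Bmp4 at -1.94). After centring each array on its median, the medians of the cell cycle and distal patterning lists were -0.48 and -0.57.

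Over all genes, the largest rises on the E14.5 array were those of Atp1b4 (7.31), Smpx (7.25), Tceal7 (7.08), Cav3 (6.52), Csrp3 (6.42) and Aspn (6.10). The largest falls besides the globin genes were those of Smc4 (-5.07), Malat1 (-4.75), Scaf11 (-4.33), Acin1 (-4.06) and Gpr50 (-4.02). The other probe sets of Smc4 (-3.63 and -2.09), Gpr50 (-3.87) and Hbb-bh1 (-6.61 and -6.57) fell by over 2-fold too. For other genes they differed: those of Scaf11 were at 0.10, -0.52 and -0.97, that of Acin1 at -0.32, and those of Malat1 at -5.31, -5.16, -0.70, -0.55 and -0.37. In total, 1833 of 12566 genes lay at least 2-fold beyond both E11.5 arrays, 1377 higher and 456 lower. With each array centred on its median the split was 2090 and 265, and the median of all genes shifted by 0.31. For 1 array against the other 2 of its group the count was 0 to 91 in 6 such sets. The array formed a control-probe batch of its own, so batch and group cannot be told apart. Its spiked-in poly-A controls averaged 5.06, against 7.16 to 7.77 on the other arrays, and its actin signal was 1.22 higher at the 3 prime than at the 5 prime end, against 0.26 to 0.49.

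From E9.7 to E10.5 the stages were compared in each tissue without a test. Lin28a, which encodes an RNA-binding protein of early embryos, differed by -4.32 in medial and by -3.95 in lateral tissue. In medial tissue its log2 level was 10.1 at E9.7, 5.81 ± 0.93 (SD, n = 3) at E10.5, 3.33 ± 0.22 (SD, n = 2) at E11.5 and 2.44 at E14.5, where the later values lie under the filter level of 4.86. These levels come from 1 of its probe sets, which differed by -2.48 from E10.5 to E11.5, while the other differed by -0.51. The list of Lin28 and early growth genes had a median of -0.47 in medial tissue, with 2 of 7 genes lower, and of -0.39 in lateral tissue, with 3 of 7 lower. The fibrillar matrix list had medians of 0.86 and 0.60, with 3 and 4 of 12 genes higher. The retinoid list had medians of 0.64 and 0.74, with 2 of 7 and 2 of 8 genes higher, and Aldh1a2 at 1.79 and 2.72. The macrophage list had medians of 0.61 and 1.0, with 2 of 8 and 2 of 6 genes higher. In each of these lists most genes were not 2-fold apart. Only 1 of the 3 E10.5 arrays per tissue shared the control-probe batch of the E9.7 arrays, so these medians mix stage and batch in part. After centring each array on its median, the medial and lateral medians were -0.80 and -0.95 for Lin28 genes, 0.64 and 0.21 for matrix, 0.44 and 0.49 for retinoid genes and 0.64 and 1.05 for macrophages.

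In medial tissue the largest rises from E9.7 were those of Alx1 (3.39), Osr1 (3.10), Rtl3 (3.01) and Gsc (2.55), and the largest falls besides Lin28a those of Wfikkn1 (-3.55), Car4 (-3.44) and Prtg (-2.67). In total, 117 of 11972 genes lay at least 2-fold beyond, 75 higher and 42 lower, and 55 and 76 with each array centred on its median, which shifted the median of all genes by -0.26. The count was 202 without medial E10.5 replicate 1, an array of low signal, and 276 with only arrays of the same control-probe batch. Set against the other 2 arrays of their own group, medial E10.5 replicates 1, 2 and 3 gave counts of 91, 2 and 19. Those sets held 1 array fewer to lie beyond.

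In lateral tissue the largest rises from E9.7 were those of Shox2 (3.80), Dlx1as (3.50), Col6a3 (3.38) and Aldh1a2 (2.72), and the largest falls besides Lin28a those of Wfikkn1 (-2.87), Prtg (-2.75) and Otx2 (-2.71). In total, 158 of 11805 genes lay at least 2-fold beyond, 112 higher and 46 lower, and 63 and 77 with each array centred on its median, which shifted the median of all genes by -0.36. The count was 270 without lateral E10.5 replicate 1 and 229 with only arrays of the same control-probe batch. Replicate 1 is the only lateral E10.5 array in the batch of the E9.7 arrays, so without it stage and batch cannot be told apart. Set against the other 2 arrays of their own group, lateral E10.5 replicates 1, 2 and 3 gave counts of 10, 1 and 0.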

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

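No test was made of the E9.7 differences in this part or of their change to E10.5. The genes were looked for after the E10.5 values were seen. For 3 genes named above, the difference between medial and lateral tissue at E9.7 had the opposite sign to that in all 9 pairs of E10.5 arrays. Fabp7, a glial marker, differed by 0.14 at E9.7 and by -2.06 at E10.5. Lum, a fibrillar matrix gene, differed by -0.15 at E9.7 and by 1.95 at E10.5. Eya1, a proximal patterning gene, differed by -0.0665 at E9.7 and by 0.54 at E10.5, where it did not pass (adjusted p = 0.135). The SD of the difference between 2 arrays of the same group, over probe sets, was between 0.212 and 0.461. The E9.7 differences of these 3 genes were smaller than that, so their sign at E9.7 is uncertain. Fabp7 and Lum were called, and in every called gene the E10.5 arrays did not overlap, so the 9 pairs add nothing for them. Among all genes called at E10.5 and measured at both stages, 516 of 552 had the same sign at E9.7. Of those with the opposite sign, the genes with the largest E9.7 differences, chosen after their values were seen, were Bmper (0.96 at E9.7 and -2.45 at E10.5), Bnc1 (0.63 and -1.15) and Timp3 (0.49 and -0.62). The E10.5 call of Bnc1 was lost with only the groups compared (adjusted p = 0.0562), without medial replicate 2 (0.118) or 3 (0.065) and without lateral replicate 1 (0.120), 2 (0.140) or 3 (0.115). That of Timp3 was lost with centring on the median (adjusted p = 0.629), without the filter on dim genes (0.0639), with only the groups compared (0.0538) and with the replicate number as a block (0.0886). It was also lost without medial replicate 2 (adjusted p = 0.151) or 3 (0.0985) and without lateral replicate 1 (0.0776), 2 (0.198) or 3 (0.143). For Bmper, Bnc1 and Timp3 too, the E9.7 sign was opposite to that in all 9 pairs of E10.5 arrays. All differences at E9.7 come from 1 array per side, and the change between stages was not tested.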

How the results depend on the processing

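The values as deposited, batch as a fixed effect, arrays of the same batch alone, the fits without the arrays of low signal and the list tests on centred values were chosen after the data were seen. Of 105 alternatives for the summary results, 79 left them within 1.5 times or on the same side, and 26 moved them. For single lists, 671 of 742 alternatives left the call as it was, 40 ended it and 31 added it. For single named genes, 2146 of 2312 left the call or the value as it was, 125 ended a call, 11 added one, 30 moved an untested value and none turned a sign. The pseudocount alternative does not apply, because the values are already log2.

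For medial against lateral at E10.5 (554 genes), the count was 358 with centring on the median, 2816 with array weights (1317 higher and 1499 lower), 300 at an adjusted p under 0.01, 2 on the values as deposited and 1254 with batch as a fixed effect. It was between 308 and 538 with 1 array left out. Without the arrays of low signal it was 712, of which 489 were also called with them. With an estimated correlation, 4 of 11 lists were called, and with 1 array left out 8 to 12. For E11.5 against E10.5 (828 genes), the count was 455 with centring, 482 with only these groups in the fit, 419 at an adjusted p under 0.01, 1 on the values as deposited and 2182 with batch as a fixed effect, and between 511 and 814 with 1 array left out. Without the arrays of low signal it was 604, of which 477 were also called with them. With an estimated correlation, 6 of 19 lists were called, and with 1 array left out 16 to 21. Where leaving out an array left 1 at E11.5, that array was assumed to vary like the other groups. A stricter adjusted p gives fewer calls by construction. With an estimated correlation, the endoderm list at E10.5 (-0.039) and the tendon list from E10.5 to E11.5 (-0.176) lost their calls. Their estimated correlations, in brackets, lay below the preset 0.01, so a higher correlation does not account for these losses. The cause of the other changes was not tested.

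Of the untested counts, medial against lateral at E9.7 (198) was 126 with the stricter filter and 26 at 4-fold. E14.5 against E11.5 (1833) was 486 at 4-fold. E10.5 against E9.7 in medial tissue (117) was 77 with the stricter filter, 202 without the array of low signal, 276 with only arrays of the same batch, 12 at 4-fold and 134 to 202 with 1 array left out. In lateral tissue (158) it was 15 at 4-fold and 174 to 270 with 1 array left out. A stricter filter and a higher fold give lower counts by construction, and fewer arrays to lie beyond give higher ones. The size of the rise differed by array, with 270 without lateral E10.5 replicate 1 against 174 and 175 without replicates 2 and 3. Replicate 1 is the only lateral E10.5 array in the control-probe batch of the E9.7 arrays. Without it, stage and batch cannot be told apart in lateral tissue.

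With the replicate number as a block, 611 genes and 10 lists were called between medial and lateral tissue at E10.5, and 1176 genes and 19 lists between E11.5 and E10.5. Arrays with the same number had deviations correlated at 0.128, -0.294 and 0.478 for the first comparison. Arrays of different number but the same control-probe batch were correlated at 0.499 (medial 2, lateral 1) and 0.263 (medial 3, lateral 2). Batch thus enters these values, and whether the number pairs the arrays cannot be told from them. For the second comparison, deviations of arrays with the same number were correlated at 0.590 and 0.389, which 2 pairs are too few to read as pairing. In that comparison arrays of the same number also belong to the same control-probe batch, so number and batch cannot be told apart. The array signal limits what low expression can show: genes under the filter level were not tested.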

Other observations

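Every test in this part except that of single probe sets was chosen only after the result was seen. Values of further lists between stages, without a test, were as follows. From E9.7 to E10.5, endothelial genes had a median of -0.51 in medial tissue and of -0.17 in lateral tissue, with none of 12 genes 2-fold apart. Neuronal genes had medians of 0.96 and 0.65, with 1 of 5 genes higher in each. Epithelial genes had a median of -0.23 in lateral tissue, with 3 of 15 genes lower. Centring each array on its median gave medians of -0.76 and -0.40 for endothelial genes, 0.90 and 0.58 for neuronal genes and -0.57 for epithelial genes.

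From E11.5 to E14.5, hedgehog genes had a median of -0.62, with 2 of 8 lower, and BMP genes a median of -0.76, with 3 of 13 lower and 2 higher. Proximal patterning genes split into 4 higher and 4 lower of 9. Neuronal genes had a median of 0.83, with 4 of 8 higher and 1 lower. After centring on the median, the list medians were -0.24 for hedgehog, -0.41 for BMP and 0.94 for neuronal genes.

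The first pattern weighed was the 554 genes called between medial and lateral tissue at E10.5. Of the 10 splits of the 6 arrays, 1 gave as many genes, the real one, and the highest count in another split was 0. Each other split mixed medial and lateral arrays, so their difference widened the spread within its groups and made low counts likely beforehand. In addition, 10 splits are too few for a share under 0.05. The tables argue against the arrays of low signal as the whole source, because 489 of the called genes were also called without them. At E9.7, on 1 array per tissue, both of control-probe batch 1 and neither used at E10.5, 516 of 552 of the called genes had the same sign, as did all 154 that were 2-fold apart there, and r across 12235 genes was 0.635. A difference between the tissues stays open as a biological explanation.

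The second pattern was the higher level of epithelial markers in medial tissue at E10.5. A lower share of mesenchyme alone would raise markers of the other cell types alike. The epithelial median lay 0.85 above the red cell median (95% interval 0.44 to 0.98) and 0.78 above that of macrophages. Red cell and macrophage markers thus did not rise with the epithelial ones. The distance to the endothelial median was 0.37, with an interval that spans 0 (-0.0377 to 0.54). These intervals come from resampling list genes, which are not independent, and hold no spread between arrays. The shares of red cells and macrophages can also differ between pieces on their own, so a lower share of mesenchyme stays open. The neural crest list had a median of -0.015, with 2 of 13 genes lower. A larger share of epithelium in medial pieces may explain the higher epithelial markers and also stays open. Of these markers, 12 of 15 were above 0 at E9.7 and 15 of 16 at E10.5. Share and expression per cell cannot be told apart here, because no cells were counted.

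The third pattern was the genes lower on the E14.5 array. The spiked-in poly-A RNAs lost more signal at the 5 prime than at the 3 prime end against E11.5, by a mean of -1.15 over 4 RNAs, which is consistent with a loss of 5 prime signal in the labelling of that array and does not show that any single gene fell for that reason. Loss of signal from single probe sets was also tested. For genes 4-fold lower, other probe sets of the same gene fell at least 2-fold in 50% of cases (40 of 80). For genes 4-fold higher, they rose at least 2-fold in 79.3% (138 of 174). Smaller moves in the same direction did not count. The difference was -29.3 percentage points (95% interval over resampled genes -40.9 to -16.2). This leaves the loss from single probe sets open, because the interval spans the bound set beforehand. For Malat1 the other probe sets differed by -5.31, -5.16, -0.70, -0.55 and -0.37, for Acin1 by -0.32 and for Scaf11 by 0.10, -0.52 and -0.97, whereas those of Smc4 (-3.63, -2.09), Gpr50 (-3.87) and Hbb-bh1 (-6.61, -6.57) moved with the gene. Stage, dissection and array batch cannot be told apart for this sample.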
